A study of Xenopus laevis with 3 samples.

How the data were processed

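RNA was extracted from whole testis of untreated Xenopus laevis males and made into poly-A selected libraries with an Illumina TruSeq mRNA kit, per the labels' protocols. The 3 libraries differ in processing date, and the labels give no other group. The libraries are named replicate 1, 2 and 3. The labels call each sample a male of outcrossed laboratory stock without stating that the animals were separate, so p-values measure only the spread between these samples.

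The deposited table gives whole-number counts per gene, per the file headers, for each library. The submitters' processing notes name HISAT2, an aligner, and featureCounts, a read counter, without versions. The strand setting, the feature type and the handling of reads that match several places are not given in the sources used here. Of the genome build, they give only a number after the word assembly in the name of the deposited table. The authors also deposited TPM, per the file headers. These values equal the counts divided by the deposited gene length and scaled to a common total of 1000000, and their sums fall short of it by 1100, 12.6 and 19.0 in the replicate 1, 2 and 3 libraries. Gene length is given by the authors in bases, and 90.9% of the lengths are multiples of 3. They were therefore taken as coding lengths without untranslated regions, which was not checked against annotated coding sequences. The deposited counts per kilobase and the deposited log2 values were not used. Of 34694 row identifiers, 34693 matched a symbol of the NCBI gene table for the assembly Xenopus_laevis_v10.1, which served for names and for which genes neighbour each other. The number in the name of the deposited table could stand for this assembly. The authors' build is not spelled out further, so no coordinates are given. Of 292 genes in the lists described below, 197 matched at least 1 row by symbol, one of them, dm-w, through its NCBI symbol xdm-w, which was looked up after the data were seen. The other 95 were not analysed here.

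Library totals were 70580016, 68378714 and 61212304 counts, so that 3 counts, used as the upper limit for a count of 0, amount to 0.0425, 0.0439 and 0.0490 CPM. Such limits and intervals cover counting error only. CPM, counts per 1000000, were computed with edgeR 4.0.16 from the counts and TMM library factors of 1.07, 0.956 and 0.979. A gene was called detected with a CPM of at least 0.5 and over 3 counts in all 3 libraries. Levels are the deposited TPM as mean ± SD over the 3 libraries. Ratios between phospholipase C genes were taken within each library on deposited TPM and tested with an exact two-sided sign-flip permutation test, which cannot go below p = 0.25 with 3 libraries.

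For homeologs, rows with the same symbol and the endings .L and .S were paired, giving 7764 pairs, and 6627 with L and S together at a CPM of at least 1 in all libraries were tested. The counts were arranged as 6 columns, L and S of each library. They were fitted with edgeR's quasi-likelihood test, with the library as a block and an offset of effective library size times coding length, and adjusted by Benjamini-Hochberg over all pairs, with a threshold of 0.05. TMM factors came from all genes of each library. The SE of a log2 ratio is its absolute value divided by the square root of the F statistic, an approximation. Ratios per library used a pseudocount of 0.5 CPM. The test was tried on simulated counts for the same 6627 pairs with 50 pairs changed at each size. At a dispersion of 0.05, a biological coefficient of variation of 22.4%, it recovered 20%, 58%, 100% and 100% of pairs changed 1.5, 2, 4 and 8 fold, with 3 false calls. That spread was lower than the 28.7% of the paired fit to the real counts and the 31.9% between libraries over all detected genes. A simulation added after the data were seen gave each pair the trended dispersion of the paired fit, from 15.8% to 43.3%. It recovered 16%, 46%, 90% and 100%, with 5 false calls. In both simulations all other pairs had equal L and S levels, while 61.1% of the real pairs were called. Recovery and false calls in the real data may therefore differ from these.

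Gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined. The lists were the phospholipase C family, X-domain phospholipases, proposed sperm factors, gamete fusion, sperm channels, phosphoinositide metabolism, markers of spermatogonia, meiosis, spermatids, Sertoli, Leydig, smooth muscle, endothelial, leukocyte, erythrocyte, adipocyte, oocyte and liver cells, W-linked genes and housekeeping genes. The gene kit stands in the lists of proposed sperm factors and spermatogonia, and tf in those of Sertoli cells and liver. Named are all phospholipase C genes with a row, the 10 genes of highest mean CPM, up to 4 detected members of each other list, the tested pairs of the phospholipase C and gamete fusion lists (none of the latter), and the 5 pairs with the widest ratio in each direction among pairs passing the test with a mean of at least 10 CPM. The 10 genes of at least 10 mean CPM with the largest SD of log2(CPM + 1) are named too. Other pairs and genes in the text were picked from the lists after their values were seen. Each list's median CPM was placed among 10000 random lists of the same size, drawn from all 34694 rows. These include the rows without a gene name, which were detected less often (39.6%, against 66.7% of all rows). Percentiles of lists of named genes are therefore high in part through this background. To compare libraries, each library's CPM + 0.5 was divided by the mean of the other 2. The median over a list was given with a bootstrap interval over its detected rows (2000 draws), with L and S copies drawn separately. Lists of immediate early genes and of further smooth muscle genes were added after the data were seen and enter only the closing observations and the plot of list medians.

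Alternatives were total-count and DESeq2 1.42.0 scaling, other detection limits and filters, DESeq2 and limma 3.58.1 in place of edgeR, TMM over the 6 columns, no length offset, no block, other pseudocounts and leaving out each library. A restriction to pairs of similar coding length was added after the data were seen. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.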

Results

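Poly-A RNA from whole testis of untreated Xenopus laevis, the African clawed frog, was sequenced in 3 libraries. Each library is labelled as coming from a male and carries its own processing date, and the 3 form a single group. The comparisons the design allows are therefore between genes within the same libraries and between one library and the others. The replicate 1, 2 and 3 libraries held 70580016, 68378714 and 61212304 counts. Of 34694 gene rows, 23153 (66.7%) were detected, meaning a CPM (count scaled to library size) of at least 0.5 and over 3 counts in all 3 libraries. Xenopus laevis is allotetraploid, and many genes have one copy on an L and one on an S chromosome. These copies are called homeologs and are written here with the endings .L and .S. A further 12269 rows (35.4%) carry locus identifiers without a gene name, and these were assigned to no family or list.

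The series title concerns PLC zeta, the sperm phospholipase C that starts calcium release in the egg at mammalian fertilisation, so the phospholipase C family was measured first. One copy, plcd4.L, which encodes the delta 4 isoform, was far more abundant than the other phospholipase C rows matched by symbol. Its level was 108 ± 23.5 TPM (abundance scaled to coding length and library size; SD, n = 3), from 12157, 18591 and 15545 counts. It held 71.4 ± 8.03% of the summed TPM of the 14 phospholipase C rows, with 63.3%, 79.3% and 71.7% in the replicate 1, 2 and 3 libraries. The other 13 rows together reached 41.9 ± 7.97 TPM (SD, n = 3).

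All 14 rows were detected, and they covered the beta, gamma and delta classes. Their list median of 10.8 CPM lay at percentile 81.8 of 10000 random lists of the same size. Those random lists were drawn from all rows. Rows without a gene name were detected less often (39.6%), which raises such percentiles for lists of named genes. Among the beta isoforms, which act downstream of G protein coupled receptors, plcb3.L stood at 8.65 ± 1.60 TPM, plcb2.L at 3.20 ± 0.255, plcb1.S at 2.996 ± 0.755, plcb4.S at 1.81 ± 0.701 and plcb4.L at 1.25 ± 0.663 (SD, n = 3 throughout). The gamma isoforms, which act downstream of tyrosine kinases, were plcg2.L at 3.36 ± 1.73 TPM, plcg1.S at 3.25 ± 1.17 and plcg1.L at 2.98 ± 0.711. The remaining delta copies were plcd1.L at 7.47 ± 2.48 TPM, plcd3.L at 4.29 ± 1.21, plcd3.S at 1.33 ± 0.338, plcd1.S at 0.945 ± 0.229 and plcd4.S at 0.421 ± 0.120. Of the genes that share only the catalytic X domain, plcxd2.L was detected at 4.90 ± 0.302 TPM. The related plcxd1.L gave 770, 1 and 136 counts in the replicate 1, 2 and 3 libraries and so was not detected in all of them, though it was without replicate 2. The genes plcz1, plce1, plch1, plch2, plcl1, plcl2 and plcxd3 matched no row by symbol and were not analysed here. Rows without a gene name were not searched for them, so this says nothing about whether the species has these genes.

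**Figure D1:**
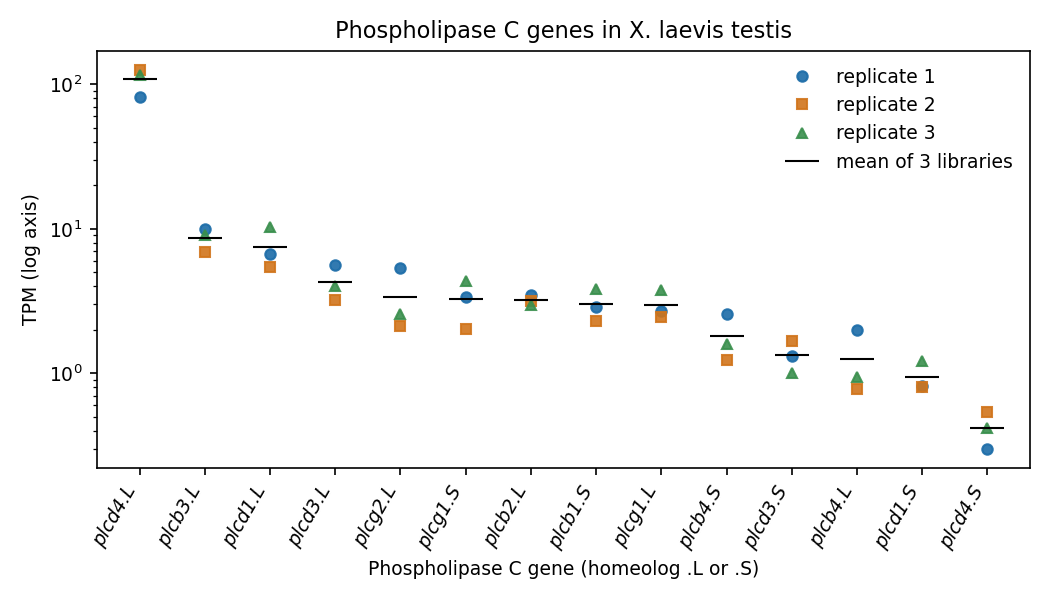
TPM on a log axis of the 14 phospholipase C rows in the 3 testis libraries, ordered by mean; symbols mark the libraries and short black lines the means. plcd4.L averaged 108 TPM and lay above every other row in all 3 libraries, followed by plcb3.L with a mean of 8.65.

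Within each library, plcd4.L exceeded each of the other 13 phospholipase C rows that were matched by symbol. Family members without such a row were not compared. The gap to plcb3.L, the next row by mean, was 3.63 ± 0.59 on the log2 scale (SD, n = 3), or 12.4-fold. It was 3.88 ± 0.57 to plcd1.L and 4.66 ± 0.73 to plcd3.L. The widest gap was to its own homeolog plcd4.S, at 8.02 ± 0.14 on the log2 scale, or 259-fold. Each of these 13 ratios was positive in 3 of 3 libraries, and the exact two-sided sign-flip permutation test gave p = 0.25, the smallest value that 3 libraries allow. The row plcd4.L was picked for its highest mean TPM in these same libraries. Positive ratios thus follow in part from that choice, and the 13 ratios share the same numerator.

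Transcripts of other genes whose products have been proposed as egg-activating factors of sperm were detected too. The gene wbp2nl, which encodes the protein known as PAWP, had 57.5 ± 5.32 TPM for wbp2nl.S and 30.9 ± 6.45 for wbp2nl.L (SD, n = 3). Citrate synthase, proposed in newts, had 65.1 ± 6.43 TPM for cs.S and 16.04 ± 3.35 for cs.L. For gnpda1, a glucosamine-6-phosphate isomerase proposed in hamster, gnpda1.L was at 60.4 ± 10.2 TPM and gnpda1.S at 14.2 ± 0.542. The receptor tyrosine kinase copies kit.S and kit.L were at 12.2 ± 7.99 and 7.33 ± 3.77 TPM, with their highest values, 21.4 and 11.4, in the replicate 1 library. All 8 rows of this list, from 4 genes, were detected, and the list median of 28.8 CPM lay at percentile 96.6 of the random lists. Counts per gene from whole testis do not show which cells hold these transcripts, nor which form of a transcript is present.

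The gamete fusion list matched 5 rows by symbol, of which 4 were detected, and the other 21 genes of that list were not analysed here. The sperm acrosome associated gene spaca9.L stood at 666 ± 47.2 TPM, while zpbp2.L, for a zona pellucida binding protein, was at 16.5 ± 8.11, izumo1r.L, the gene of the egg receptor of Izumo1, at 21.1 ± 10.14 and pgap1.L at 4.50 ± 1.57 (SD, n = 3). The hyaluronidase gene spam1.L, with 19, 138 and 66 counts, was not detected in all 3 libraries. The list of sperm channels and their partners matched 11 rows of 6 genes by symbol, of which 8 were detected. The other 14 genes of that list, among them the catsper genes, were not analysed here. The proton channel gene hvcn1 led with 126 ± 56.0 TPM for hvcn1.L and 64.6 ± 13.1 for hvcn1.S, followed by the cation channel genes pkd2.L at 16.4 ± 3.44 and trpv4.S at 3.38 ± 1.64. Not detected were lrrc52.L, lrrc52.S and pkd2l1.S.

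Genes of phosphoinositide metabolism and of signalling around phospholipase C were detected in 36 of 36 rows. The lipid kinase copies pip4k2c.S and pip4k2b.L had 203 ± 32.7 and 137 ± 13.4 TPM, pip4k2c.L had 74.2 ± 34.5 and pi4ka.S had 21.1 ± 2.28 (SD, n = 3). The list median of 16.7 CPM lay at percentile 99.4 of the random lists.

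Genes of meiosis and of sperm formation had the highest medians of the cell type lists. Of 31 spermatid rows, 30 were detected, with a median of 142 CPM, and of 19 meiosis rows, 18 were detected, with a median of 106 CPM. Both medians lay at percentile 100 of the random lists. They cover matched rows only, since 17 of 40 spermatid genes and 10 of 27 meiosis genes matched no row by symbol. The outer dense fibre gene odf2.L reached 302 ± 48.4 TPM, tcte1.L, for a subunit of the axonemal dynein regulatory complex, 367 ± 60.6, cfap44.L 74.5 ± 2.13 and the tektin gene tekt1.L 379 ± 74.8 (SD, n = 3). Among meiosis genes, hormad1.S was at 229 ± 23.2 TPM, the cyclin gene ccna1.L at 167 ± 43.8, and the meiotic cohesin genes smc1b.L at 96.4 ± 9.11 and stag3.L at 62.9 ± 16.9. Of 24 rows for spermatogonia and early germ cells, 19 were detected. The RNA-binding protein gene dazl.L was at 1181 ± 133 TPM, the RNA helicase copies ddx4.L and ddx4.S at 397 ± 72.0 and 140 ± 27.6, and the transcription factor gene dmrt1.L at 238 ± 47.2. Not detected in all 3 libraries were nanos1.L, nanos3.L, nanos3.S, ret.S, sall4.S, spo11.S and meig1.L.

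Somatic cells of the testis were represented as well. Sertoli cell genes were detected in 23 of 26 rows, with clu.L at 349 ± 72.8 TPM, the inhibin gene inha.L at 204 ± 85.5, sox9.S at 32.5 ± 6.14 and the anti-Müllerian hormone gene amh.S at 24.2 ± 8.13 (SD, n = 3). Neither copy of gdnf nor ptgds.S was detected. Leydig cell genes were detected in 15 of 15 rows, led by the steroid synthesis genes cyp17a1.L at 534 ± 186 TPM, star.L at 140 ± 102 and hsd3b1.L at 108 ± 88.2, and the lipoprotein receptor gene scarb1.L at 68.3 ± 34.3. Smooth muscle genes, which are also expressed by the peritubular cells of the testis, were detected in 10 of 10 rows. Their copies acta2.S, acta2.L and tagln.L had 144 ± 132, 133 ± 144 and 134 ± 137 TPM, and myh11.L had 27.4 ± 12.2. Endothelial genes were detected in 13 of 13 rows at a median of 7.28 CPM, with pecam1.L at 13.4 ± 3.72 TPM, tie1.L at 5.88 ± 0.800, kdr.S at 4.52 ± 1.39 and vwf.L at 2.13 ± 0.269.

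Markers of blood cells, fat, oocytes and liver were measured as well. Leukocyte genes were detected in 15 of 18 rows at a median of 3.40 CPM, with mpo.S at 44.8 ± 74.4 TPM, cd74.S at 30.8 ± 11.2, cd74.L at 28.4 ± 15.4 and spi1.L at 13.4 ± 5.99 (SD, n = 3). Erythrocyte genes were detected in 7 of 16 rows, and in 12 at a CPM of at least 0.1, with the globin genes hba1.L at 47.4 ± 18.2 TPM, hbg1.L at 42.5 ± 17.8 and hba1.S at 7.35 ± 1.24, and gata1.L at 4.11 ± 0.228. Adipocyte genes were detected in 8 of 12 rows, with fabp4.L at 50.6 ± 24.7 TPM, cidec.S at 49.2 ± 15.1, lpl.L at 25.9 ± 14.3 and lpl.S at 21.2 ± 5.30. Oocyte genes were detected in 5 of 13 rows, and in 11 at a CPM of at least 0.1, with figla.L at 103 ± 21.9 TPM, gtf3a.L at 70.3 ± 17.0, the egg coat genes zp4.L at 13.97 ± 1.82 and zpd.L at 10.7 ± 5.66. Neither copy of the oocyte growth factor gene gdf9 was detected at 0.5 CPM, nor was bmp15.L. Liver genes were detected in 8 of 16 rows, and in 13 at a CPM of at least 0.1, with fgb.L at 6.87 ± 3.07 TPM, alb.S at 6.83 ± 4.47, vtga2.L at 1.74 ± 1.08 and vtgb1.L at 0.967 ± 0.302. The W-linked, female-determining gene xdm-w had 0 counts in every library, which allows at most 0.0425, 0.0439 and 0.0490 CPM in the replicate 1, 2 and 3 libraries. Housekeeping genes were detected in 16 of 16 rows at a median of 588 CPM, led by ubc.S, eef1a1.L, eef1a1.S and rpl8.S, the last at 1164 ± 72.8 TPM. Among the random lists, the medians of the smooth muscle, Leydig, Sertoli, spermatogonia, gamete fusion and endothelial lists lay at percentiles 99.96, 97.4, 95.8, 86.7, 78.6 and 66.6. Those of the sperm channel, adipocyte, leukocyte and X-domain phospholipase lists lay at 43.03, 42.96, 36.3 and 32.2, and those of the erythrocyte, liver and oocyte lists at 9.56, 9.55 and 5.93, against 100 for housekeeping genes.

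The 10 most abundant rows by mean CPM included the mitochondrial COX1 at 8280 ± 295 CPM, the ubiquitin gene ubc.S at 5626 ± 1137, the elongation factor copies eef1a1.L and eef1a1.S at 3494 ± 587 and 3045 ± 661, and the heat shock protein gene hspa1l.S at 2746 ± 424 (SD, n = 3). The metalloprotease gene astl2b.L had 5081 ± 1816 CPM, tmem254.S had 3180 ± 681 and rflcii.S had 2747 ± 2510. Another 2 of the 10, LOC100192369 and LOC108716425, have no gene name and stood at 9903 ± 4392 and 3897 ± 961 CPM. By fold, rflcii.S varied most among them, with 1733, 4235 and 12040 TPM in the replicate 1, 2 and 3 libraries.

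Homeolog copies often differed in level, and plcd4 was among the pairs with the widest difference. Of 7764 L and S pairs, 6627 had enough counts to test, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4049 (61.1%), with L higher in 2283 and S higher in 1766. For plcd4, the log2 ratio of L to S was 8.01 (SE 0.156, adjusted p = 0.000153, edgeR), rank 26 by absolute fitted value among the pairs tested. Pairs with 0 counts in one copy are ranked too, though their counts give only a lower bound for the ratio. Copies from L were also higher for plcd1, by 2.96 on the log2 scale (SE 0.209, adjusted p = 0.00055, edgeR), and for plcd3, by 1.68 (SE 0.326, adjusted p = 0.00857, edgeR), each in 3 of 3 libraries. The pairs plcb4, at -0.59 (SE 0.235, adjusted p = 0.0789, edgeR), and plcg1, at -0.08 (SE 0.208, adjusted p = 0.744, edgeR), did not pass. Adjusted over the list alone, the same count of 3 of 5 phospholipase C pairs had L higher.

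**Figure D2:**
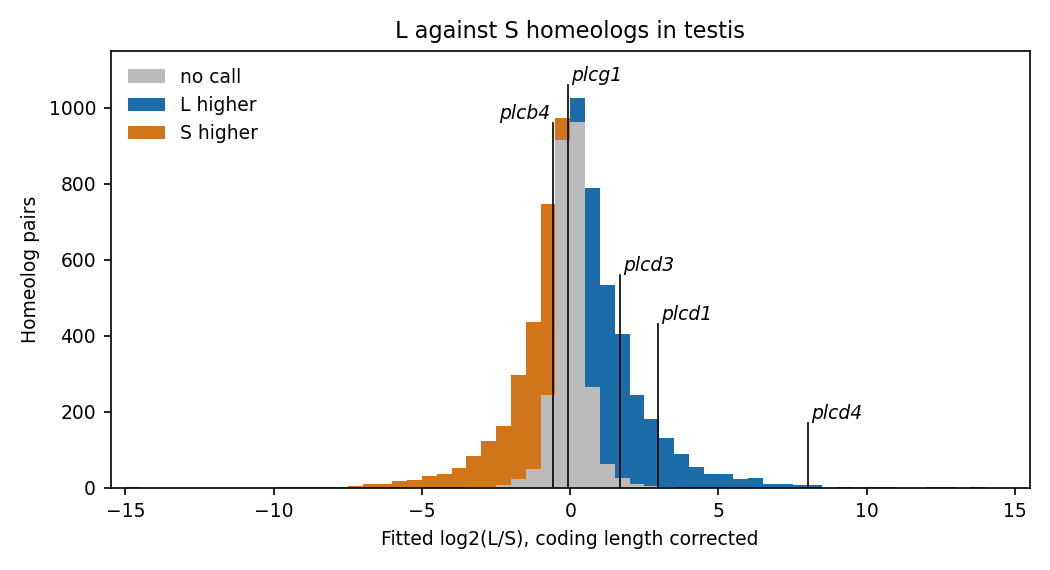
Histogram of the fitted log2 ratio of L to S, corrected for coding length, over the 6627 homeolog pairs tested; bars are coloured by the call at an adjusted p under 0.05 and lines mark the 5 phospholipase C pairs. The plcd4 pair lies at 8.01, in the right tail, and 105 called pairs have an absolute value above 6.

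Pairs in the other lists went both ways. Of the proposed sperm factors, gnpda1 had L higher by 2.08 on the log2 scale, while cs, wbp2nl and kit had S higher, at -2.04, -0.92 and -0.68 (adjusted p from 0.000542 to 0.0273, edgeR); all 4 pairs passed, also adjusted over the list alone. Of 3 sperm channel pairs, hvcn1 had L higher (0.88) and atp2b4 had S higher (-1.30). Phosphoinositide genes had L higher in 6 of 15 pairs, among them pip4k2b (2.26), and S higher in 4, among them pip4k2c (-1.54) and pi4ka (-0.92). In the spermatid list L was higher in 5 of 8 pairs, among them tekt1 (3.97), and S in 1, tekt2 (-1.03). L was higher in 3 of 8 pairs of the spermatogonia list, ddx4 (1.51), ret (4.26) and dmrt1 (1.104), and S in 1, kit (-0.68). L was higher in 2 of 2 pairs of the meiosis list, ccna1 (3.02) and spo11 (8.45). Somatic lists gave L higher in 3 of 10 Sertoli, 1 of 4 Leydig, 3 of 5 smooth muscle and 3 of 5 endothelial pairs, against 1, 0, 0 and 0 with S higher. For leukocytes, L was higher in 2 of 7 pairs and S in 1, and for housekeeping genes in 2 of 7 and 1. In both of these lists no pair with S higher was left when adjusted over the list alone. The other lists kept their counts, which were L higher in 2 of 3 erythrocyte, 2 of 4 adipocyte, 1 of 1 oocyte and 3 of 3 liver pairs, and S higher in 1 adipocyte pair.

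In the pairs with the widest fitted differences, one copy was nearly without counts. c2orf76.L stood at 72.4 ± 24.4 TPM and fam214b.L at 7.17 ± 1.85 (SD, n = 3), against 0 counts for their S copies, and klhl24.L at 14.4 ± 2.61 against 0 counts for an S model with a coding length of only 67 bases. Set against 3 counts over all libraries, L was at least 2050, 824 and 61.4 times higher, per base of coding length. The fitted log2 ratio of klhl24, 12.72, was 0.887 with limma, so its place among the widest pairs depends on the fit. The cilium gene ttc29.L was at 130 ± 15.3 TPM, and ttc29.S had 3 counts in all, a ratio of 5710 with a counting interval from 1950 to 27700. For cilp, L was higher by 10.76 on the log2 scale (SE 0.417, adjusted p = 0.000289, edgeR). In the other direction, sh3bgrl3.S was at 243 ± 44.7 TPM against 0 counts for sh3bgrl3.L, at least 3710 times higher. The log2 ratios of nat8.1, c1orf194, pglyrp1 and cops9 were -9.64, -9.18, -9.03 and -8.87, with adjusted p from 0.000199 to 0.000498 (edgeR) and S above L in 3 of 3 libraries. Leaving out a library kept these calls but moved 3 of the ratios by over 1.5 times, cilp to 10.17 without replicate 1, nat8.1 to -10.53 without replicate 2, and the fitted ttc29 ratio of 12.36 to 11.69 without replicate 1 and 13.29 without replicate 2. Of the 4049 called pairs, 1396 differed over 4-fold, 850 with L and 546 with S higher.

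Over the 6627 pairs tested, the L copies were slightly more abundant than the S copies. The median log2 ratio of L to S was 0.136 ± 0.00143 (SD, n = 3), or 1.099-fold, and L exceeded S in 54.2 ± 0.668% of pairs, in the same direction in 3 of 3 libraries. The exact two-sided sign-flip permutation test gave p = 0.25 for both, the smallest value possible. Scaling the L and S columns separately by TMM, which centres such a difference, moved the median fitted log2 ratio from 0.15 to 0.01 and the calls to 2053 with L and 2025 with S higher. Reads that match both copies could have been dropped or split when they were counted, so ratios of near-identical pairs are uncertain.

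Between libraries, smooth muscle genes differed more than any other list. The 10 detected rows of this list were L and S copies of 5 genes. Their median log2 ratio to the mean of the other 2 libraries was 2.07 in the replicate 3 library, where 10 of 10 were highest. In the replicate 1 library it was -3.24, and 8 of 10 were lowest. The actin copy acta2.L had 18.8, 84.3 and 295 TPM in the replicate 1, 2 and 3 libraries, and the calponin copy cnn1.L 4.97, 22.4 and 67.1. Leydig cell genes had a median log2 ratio of 0.29 in the replicate 3 library, where 8 of 15 rows were highest, and -0.53 in the replicate 1 library. Members of that list differed among themselves, with star.L at 47.0, 124 and 249 TPM and hsd3b1.L at 36.4, 80.6 and 206, while fdx1.L, for the electron carrier adrenodoxin, was at 36.3, 31.5 and 31.9. Leukocyte genes had a median of 0.73 in the replicate 3 library and were highest there in 12 of 15 rows.

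Germ cell lists differed less. Spermatid genes had a median log2 ratio of 0.41 in the replicate 2 library, with 18 of 30 rows highest, and -0.28 in the replicate 1 library. Meiosis genes stood at 0.26 in the replicate 2 library and spermatogonia genes at 0.23 in the replicate 1 library. Sertoli cell genes were lowest in the replicate 2 library, at -0.50, in 16 of 23 rows, and at 0.24 and 0.09 in the replicate 1 and 3 libraries. Endothelial genes were at 0.29 in the replicate 3 library. The 4 detected gamete fusion genes had a median of -0.92 in the replicate 3 library (95% bootstrap interval -1.38 to 0.09), where 3 of them were lowest. Among these, izumo1r.L had 24.4, 29.1 and 9.67 TPM and zpbp2.L 19.0, 23.1 and 7.43 in the replicate 1, 2 and 3 libraries. The most abundant of the 4, spaca9.L, was not lowest there, at 615, 709 and 673 TPM. Phospholipase C genes had medians of -0.14, -0.38 and 0.10 in the replicate 1, 2 and 3 libraries. In the replicate 2 library 8 of their 14 rows were lowest (95% bootstrap interval -0.59 to 0.09, percentile 2.57 of random lists of matched expression). Another 4 rows were highest there. Among these was plcd4.L, the most abundant, at 81.2, 126 and 116 TPM in the replicate 1, 2 and 3 libraries. The list median therefore does not describe the summed level of the family. The proposed sperm factors stood at 0.08, -0.33 and 0.06, with 7 of 8 rows lowest in the replicate 2 library (-0.86 to -0.10, percentile 2.71). Medians lay between -0.12 and 0.18 for sperm channel genes, between -0.10 and 0.10 for phosphoinositide genes and between -0.14 and 0.09 for housekeeping genes. The sperm channel rows moved in opposite directions. In the replicate 1 library 4 of 8 were highest and 3 lowest (95% bootstrap interval -1.30 to 0.70). In their own highest library, the erythrocyte list reached 0.27 in the replicate 2 library, and the adipocyte and oocyte lists 0.30 and 0.13 in the replicate 1 library. In their lowest, the erythrocyte and oocyte lists had -0.32 and -0.16 in the replicate 3 library and the adipocyte list -0.40 in the replicate 2 library. Liver genes had -0.08, -0.26 and -0.10 in the replicate 1, 2 and 3 libraries. With total counts in place of TMM, which moved the median over all detected genes in the replicate 1 library from -0.02 to 0.12, the meiosis median there went from -0.13 to 0.01, the endothelial one from -0.09 to 0.04 and the liver one from -0.08 to 0.03. With 1 library per date, animal and date cannot be told apart, and these medians describe the libraries without a test.

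**Figure D3:**
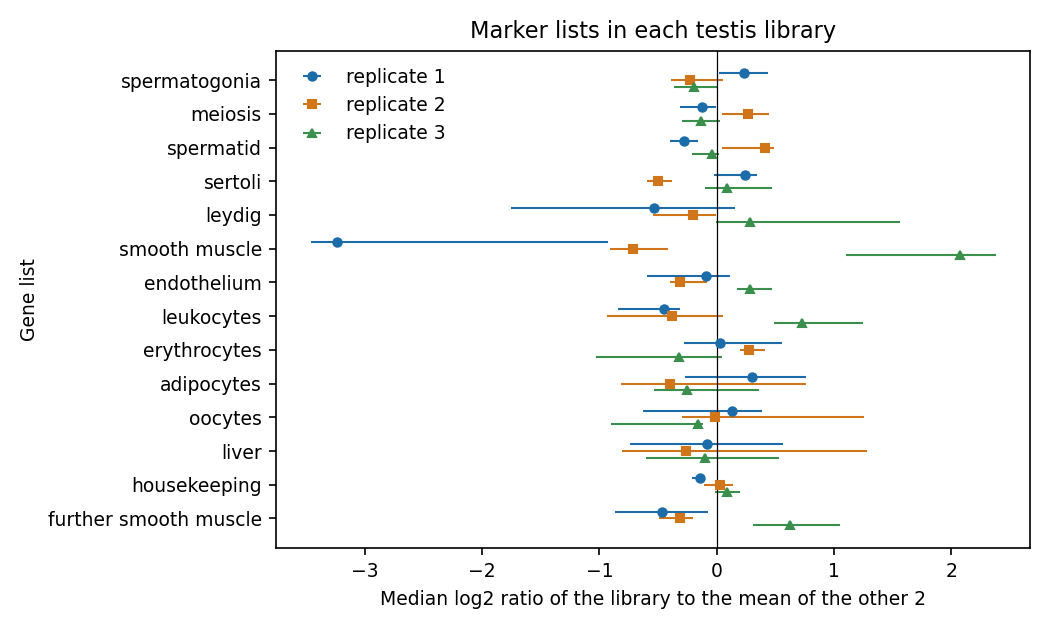
Median over detected rows of the log2 ratio of each testis library to the mean of the other 2, for 14 gene lists. Bars are 95% bootstrap intervals over rows, with L and S copies drawn separately. Smooth muscle genes lie at 2.07 in the replicate 3 library and -3.24 in the replicate 1 library, while housekeeping genes lie between -0.14 and 0.09.

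Across all 34694 genes, log2(CPM + 1) correlated between libraries with Pearson's r of 0.973, 0.977 and 0.977 and Spearman's rho of 0.969, 0.973 and 0.972, over genes, which are not independent replicates. The biological coefficient of variation was 31.9% as a single common value over all detected genes. Fitted as a trend over expression level, its median was 40.5% for genes at 1 to 10 CPM, 26.2% at 10 to 100 CPM and 23.6% above 100 CPM. Single genes departed further. The neutrophil enzyme gene mpo.S had 4.23, 3.35 and 290 CPM in the replicate 1, 2 and 3 libraries. The activin subunit gene inhbc.2.L had 0.0398, 33.2 and 0.284 CPM, clvs1.S 0.225, 48.7 and 0.334, cyp2a6.12.L 0.544, 36.4 and 57.1, atf6.S 1.22, 68.6 and 32.9 and dtx3l.L 49.5, 0.352 and 18.1. The others of the 10 most variable were LOC108708376, LOC108697233 and LOC121397361, highest in the replicate 3 library at 155, 76.3 and 50.9 CPM, and LOC108718612, lowest in the replicate 2 library at 0.535 CPM. Of 13679 genes with a mean of at least 10 CPM, 261 (1.91%) had an SD of log2(CPM + 1) over 1, against a median of 0.24.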

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

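The restriction to pairs of similar coding length was chosen after the data were seen; the other alternatives were planned. plcd4.L ranked first among phospholipase C rows under each alternative run for the ranking. The totals of pairs called in each direction, the 23153 detected rows and the detected rows of the lists stayed within 1.5 times of the reported counts under the alternatives run for them, except for 4 lists. At a CPM of at least 0.1, 12 of 16 erythrocyte, 11 of 13 oocyte and 13 of 16 liver rows were detected, against 7, 5 and 8. With 1 library enough for detection there were 12 erythrocyte and 10 oocyte rows and 2 X-domain phospholipase rows, against 1; the latter count was 1 to 2 when a library was left out, and 2 without replicate 2. The lower limits themselves admit these rows. Calls with L higher ranged from 1727 to 2436 and with S higher from 1351 to 2025; without the library block they were 2114 and 1642. Of 160 alternatives for 15 named pairs, 157 kept direction and side of the threshold. The plcd4 ratio lay between 7.36, with limma and a pseudocount of 0.5, and 8.09. The plcb4 pair passed with limma (-0.54, adjusted p = 0.0337) and with TMM over the 6 columns (-0.73, adjusted p = 0.0426), against adjusted p up to 0.303 under the others. The plcg1 pair, never called, lay between -0.26 and 0.0335, above 0 without replicate 1; the cause was not tested. The median ratio of L to S, 0.136, became 0.145 without gene length, 0.110 at a CPM of at least 10, 0.0990 with all pairs of any count, 0.144 with a pseudocount of 0.1 and 0.146 for pairs whose coding lengths differ by at most 10%; the cause was not tested. It stayed between 0.135 and 0.137 when a library was left out. The lowest correlation between libraries, 0.973, became 0.969 with a pseudocount of 0.1 and 0.949 for genes with a CPM of at least 1, a narrower range of levels. Depth limits plcd4.S, with 45 to 80 counts per library, and pairs with a copy near 0, whose fitted ratios depend on the pseudocount.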

Other observations

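Tests of the germ cell share, of Leydig cells and of neighbouring silent genes were chosen after the result was seen; so were the lists of immediate early and further smooth muscle genes and the criteria for silent genes.

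Some genes were nearly without transcripts in one library and expressed in the other 2. Counting genes at 5 CPM or more in both other libraries and over 16-fold lower in one, there were 38, of which 17 were low in the replicate 1 library, 15 in the replicate 2 library and 6 in the replicate 3 library, among 15889 to 16159 eligible genes per library. The pyruvate dehydrogenase subunit gene pdha1.S had 0.703, 19.7 and 30.5 CPM in the replicate 1, 2 and 3 libraries, and meig1.L, whose mammalian counterpart is needed for sperm formation, had 0.146, 21.7 and 23.8. The sorbitol dehydrogenase gene sord.S had 11.7, 22.6 and 0 CPM, and the zinc finger gene znf770.S 12.0, 10.8 and 0. The neighbours parp9.L and dtx3l.L, whose products form a complex in mammals, were both low in the replicate 2 library, at 0 and 0.352 CPM. These genes were chosen after their values were seen.

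Reads of a low copy could have been counted on its homeolog, if the animal's sequence differs from the reference. For the 12 of these genes with a homeolog row, the median share of the missing CPM that the homeolog gained was -0.00834 (95% bootstrap interval -0.155 to 0.0492), near 0, which argues against that explanation as the general cause among them, although the share was 0.349 for pdha1.S, where it stays open for part of the loss. A missing or changed chromosome stretch could silence neighbouring genes together. Leaving out parp9.L with dtx3l.L, the pair that prompted this test, there was 1 neighbouring pair of silent genes in the same library among the other 36, LOC121400473 with pdha1.S, and 1.62% of 10000 random draws had as many. A single pair is too few to decide, so neighbouring genes silent together and variants of single genes both stay open.

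Smooth muscle genes, and some Leydig cell genes such as star.L and hsd3b1.L, were higher in the replicate 3 library, and this could come from a lower share of germ cells, which would raise all somatic markers alike. The Sertoli list had a median log2 ratio of 0.0907 there (95% bootstrap interval -0.10 to 0.47) and the endothelial list 0.29 (0.17 to 0.47). Both lay apart from 2.07 (1.11 to 2.38) for smooth muscle, which argues against that explanation as the whole cause. Leukocyte genes, however, stood at 0.73 (0.48 to 1.24). The 10 smooth muscle rows are copies of 5 genes and rows were drawn separately, so these intervals may be too narrow. More smooth muscle, such as vessel wall, capsule or peritubular tissue, in that sample is a candidate explanation for part of the difference: a further list of smooth muscle genes, written before its values were looked at, had a median of 0.63 (0.31 to 1.05) over 24 detected rows, percentile 100 of random lists of matched expression, with tpm2.S at 18.6, 47.0 and 168 TPM in the replicate 1, 2 and 3 libraries. That median is below the leukocyte one and its interval lies wholly below that of the smooth muscle list, so the further genes did not rise alike with the first, and whether other cells also express them was not tested. In the replicate 3 library 8 of 15 Leydig rows were highest and others, such as fdx1.L and scarb1.L, were not, which does not decide whether it held more Leydig cells. Much of the list consists of steroid synthesis genes, so it cannot tell more Leydig cells from higher steroid synthesis per cell. Animal, date and dissection stay open too.

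Some immediate early genes, which respond within minutes to stress and handling of tissue, were high in the replicate 1 library. There fos.S had 82.9, 8.58 and 4.67 TPM in the replicate 1, 2 and 3 libraries and egr1.L 34.2, 4.35 and 1.86. The rest of the list, without both copies of fos and egr1, had a median log2 ratio of 0.35 in that library (95% bootstrap interval 0.22 to 0.68), percentile 99.99 of the random lists of matched expression, with 24 of 36 rows highest and 9 lowest; among the highest were junb.S at 72.0, 12.4 and 10.2 TPM and socs3.S at 90.1, 23.7 and 8.10. Other lists were higher there by similar amounts with overlapping intervals, at medians of 0.23 for spermatogonia genes (0.02 to 0.43, percentile 99.9), 0.24 for Sertoli cell genes (-0.02 to 0.35, percentile 99.1) and 0.30 for adipocyte genes (-0.27 to 0.76, percentile 95.9). An immediate early response of most of the list in that sample, such as after a longer time between dissection and lysis, which the labels do not give, is therefore one candidate explanation, and a different cell content stays open beside it.

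For the count of homeolog pairs, the 6 columns can be split into 2 groups of 3 in 10 ways. The real split called 4049 pairs and was the 1 split with as many; the highest of the others called 0. With 10 splits no share under 0.05 is possible. Every other split also puts L and S columns in both groups, so real differences between L and S add to the spread within groups. Some of them part the columns of only 1 library. Few calls in the other splits were thus built in, and the comparison cannot decide whether chance gave the real count.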
